A study of Caenorhabditis elegans with 11 samples.

How the data were processed

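RNA from whole adult Caenorhabditis elegans was sequenced on an Illumina instrument. The 11 libraries fall into 5 groups: N2 (the wild-type strain) on K12 bacteria, early (n = 3) and late (n = 2), N2 on tnaA bacteria, early (n = 2) and late (n = 2), and ahr-1 mutants on K12, late (n = 2). K12 is an Escherichia coli strain that makes indole, and the tnaA strain lacks tryptophanase, the enzyme that releases indole from tryptophan. The ahr-1 allele, ia3, is a loss-of-function allele of the worm aryl hydrocarbon receptor. Per the labels, worms were kept on their bacteria from the embryo onward, each sample was a biological replicate of pooled adults, and RNA was taken with Trizol and a column kit. Growth was at 16 °C in all groups, with about 150 worms per sample. The labels give 12 days for late worms and 3 days for early worms, whereas the text on the design calls the early worms 2-day adults, so the early age is open between these values.

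The authors deposited one table of raw read counts per gene for each library, which they made with Trim Galore, STAR and HTSeq 0.6.1p2. Versions of the other tools, their settings, the genome build, the annotation and the strand setting are not given in the sources used here, so no coordinates are printed, and reads of overlapping genes on opposite strands cannot be told apart. The counts held 42048 genes and 2 summary lines, for reads in no gene and for ambiguous reads. Gene symbols are printed as in the deposited counts, of which 38843 match a current symbol. The authors also deposited a pair of DESeq2 tables for the late comparisons, with log2 fold changes and adjusted p-values of the genes they listed. The 8 columns of normalised values per sample in those tables were not used here.

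Total gene counts per library ran from 8.31 to 15.3, in units of 1e6 reads, so that 1 read stood for 0.0572 to 0.103 counts per 1e6 reads (CPM). Replicates of a group varied more than counting error alone, with chi-square over degrees of freedom between 2.90 and 5.42 for pairs of libraries, over genes with at least 20 reads. Reads carried no molecular identifiers, so counting intervals and floors cover counting error only.

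Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr by group with its minimum count of 10 (15133 genes) were scaled with TMM and fitted in 1 quasi-likelihood model with a mean per group over all 11 libraries, which left 6 residual degrees of freedom. The quasi-likelihood F test is two-sided. P-values were adjusted by Benjamini-Hochberg over all genes tested within each of the 6 comparisons, and a gene is called at an adjusted p under 0.05. The comparisons were late K12 against late tnaA, late ahr-1 against late N2 on K12, late against early on K12, late against early on tnaA, early K12 against early tnaA, and the difference between both ageing changes. A log2 fold change is given with its standard error, the size of the unshrunk change over the square root of F, and a CPM value with its SD over the group's libraries, with n as above. Where a group had 0 reads, the fold is a lower bound against a floor of 3 counts over the group, and where it had 1 to 3 reads, the ratio is given with its exact 95% counting interval.

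Before the data were examined, 33 gene lists, the groups, the tests, the rule for named genes and most alternatives were fixed. Of the given list members, 11 were not found among the gene symbols. Lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes, adjusted over the 33 lists of a comparison, then with a correlation estimated per list. Camera compares a list with all other genes, whereas fry, run beside it, asks whether the members move on balance one way. The preset correlation called 13, 14, 18, 15, 8 and 14 lists in the order of the comparisons above, and 0 lists in every comparison with an estimated correlation, where the lowest adjusted p was 0.340. Fry called 11, 14, 29, 31, 0 and 0 lists.

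Named genes were the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries of both groups, for the late comparisons and for ageing on K12, and 5 each for the others. Up to 4 called members of each list with the smallest p were added, and ahr-1, aha-1 and the 6 vitellogenin genes always. The text gives a part of these, members of lists first, and passes over genes known only by a sequence name. Correlations across genes use log2 fold changes with a prior count of 2 for genes with a mean of at least 1 CPM. Genes are not independent replicates, so these correlations are descriptions. For pairs of comparisons that share libraries, 20 simulated data sets gave the correlation that sharing alone makes when no gene differs. Real changes add variance, so sharing weighs less on r in the data, and covariances were compared as well.

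The calls were tested on simulated data with 200 changed genes. With the noise of each gene taken as its own dispersion, 38.7 to 44.6% of changes of 0.5 on the log2 scale and 57.9 to 63.8% of changes of 1 were recovered, and 3.85 to 9.43% of calls were false. With the larger of the own and the trended dispersion, 35.1 to 43.6% and 60.4 to 66.7% were recovered, and 4.17 to 10.5% of calls were false. The first noise level was chosen after the false calls with the second had been seen. A simulated list of 30 genes raised by 0.5 was called at both noise levels, and 0 unchanged lists were. The simulated genes were drawn independently, so this could not show false list calls that come from correlation between genes.

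The alternatives were DESeq2 1.42.0, RLE size factors in edgeR, no filter on low counts, a mean of at least 5 CPM, only the libraries of the groups compared, the replicate number as a block, a prior count of 0.5, and leaving out each library in turn. Scaling by library size only, thinning all libraries to the lowest total, and giving each late K12 library to only 1 of the comparisons that share it were added after the data had been seen. The test of germline tissue share was replaced once: the first form, the share of the pattern's own members above 0, could not have come out otherwise, and the second form, on somatic lists, was written with the medians of those lists already in the tables. A list of male soma genes and a list of embryonic patterning genes were written for the closing tests after the first results had been seen but before the values of those lists were looked at.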

Results

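The series measured how indole made by gut bacteria and the receptor ahr-1 bear on the transcriptome of ageing worms. Gene counts, in units of 1e6 reads, were 15.3 and 14.5 for late K12 replicates 1 and 3, 14.7 and 8.31 for late tnaA replicates 2 and 3, 10.4 and 11.9 for late ahr-1 replicates 1 and 3, 14.4, 14.8 and 14.7 for early K12 replicates 1 to 3, and 15.2 and 14.9 for early tnaA replicates 2 and 3. Reads outside genes made up 14.8% and 9.26% of late tnaA replicates 3 and 2, 13.8% and 11.6% of late ahr-1 replicates 1 and 3, 8.56% and 8.27% of late K12 replicates 1 and 3, and 6.14 to 7.19% of the early libraries. Ambiguous reads were 0.267 to 0.296% of every library. Between 16780 and 20983 genes had a read.

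Reads of the 6 vitellogenin genes, which code for yolk proteins, took 6.47 to 6.76% of gene counts in early libraries and 1.35 to 1.72% in late ones. TMM factors were 0.820 to 0.877 in early and 1.14 to 1.17 in late libraries. The first principal component held 79.3% of the variance and separated early libraries (-105 to -89.5) from late ones (67.6 to 97.5). The second held 8.23%, with both late ahr-1 libraries at 46.2 and 45, early tnaA replicate 2 at 28.9, early K12 replicate 3 at 24.1 and the other libraries at or below -5.41. In that order, the libraries high on it had mean log2 CPM of the sperm list of 1.56, 1.75, 1.93 and 1.83. The other libraries had at most 0.49, so this component followed sperm transcripts and did not set the mutant apart from all N2 libraries.

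**Figure D1:**
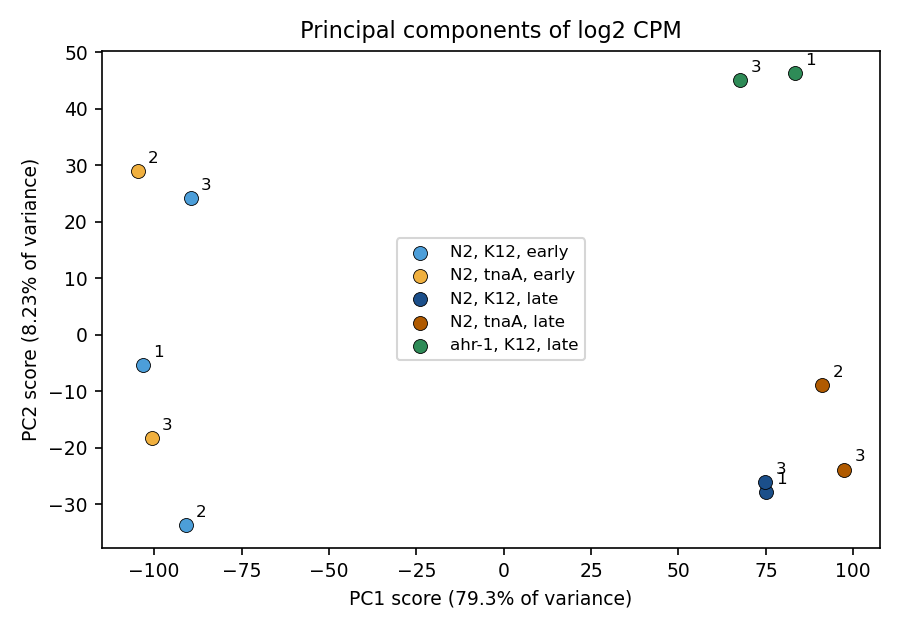
The first (79.3% of the variance) and second (8.23%) principal components of log2 CPM are plotted for the 11 libraries, 1 point each, coloured by group. Early and late libraries lie on opposite sides of the first component, and both late ahr-1 libraries (46.2 and 45) lie above the late N2 libraries on the second. Early tnaA replicate 2 (28.9) and early K12 replicate 3 (24.1) also lie high on the second.

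In late worms, transcripts of the germline and of oocytes were more abundant on indole-producing K12 than on tnaA bacteria. The germline Argonaute csr-1 stood at 303 ± 8.10 CPM on K12 and 215 ± 5.03 on tnaA (log2 fold change 0.50 ± 0.06, adjusted p = 0.001), and the eggshell proteoglycan gene cpg-1 at 1689 ± 88.0 and 1171 ± 75.6 (0.53 ± 0.08, adjusted p = 0.00712). Of the oogenesis and eggshell list, 22 of 26 measured members rose, with 22 adjusted over the list alone and a median of 0.40, among them the egg activation gene egg-3 (0.41 ± 0.06) and the Y-box protein gene cey-2 (0.56 ± 0.09). In the germline and P granule list, 21 of 25 rose, with 24 adjusted over the list alone and a median of 0.40, among them the P granule genes pgl-3 (0.40 ± 0.06) and glh-2 (0.48 ± 0.08). Of 31 meiosis genes, 17 rose, with 26 adjusted over the list alone and a median of 0.35, among them zim-3 of the pairing centres (0.49 ± 0.07), syp-2 of the synaptonemal complex (0.49 ± 0.07) and htp-1 of the chromosome axis (0.52 ± 0.09). Camera called these 3 lists higher (adjusted p = 6.45e-17, 3.48e-21 and 6.45e-17). The calls were lost at adjusted p = 0.388, 0.365 and 0.365 with an estimated correlation. Of the germline list, 1 member was called without late tnaA replicate 3, 1 without late K12 replicate 1, 14 without late tnaA replicate 2 and 18 without late K12 replicate 3, while camera called the 3 lists in each of these fits. All calls of oogenesis and meiosis genes were lost without late tnaA replicate 3 or late K12 replicate 1, and 13 oogenesis genes were called without late tnaA replicate 2.

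This comparison asked what the loss of bacterial indole changes in old worms. Of 15133 genes tested, 886 were higher and 646 lower on K12 than on tnaA, 62 and 37 of them by at least 2-fold. The balance turned with the scaling, with 1152 higher and 585 lower for RLE size factors and 839 and 865 for library size only. The counts were 10 higher and 15 lower without late tnaA replicate 3, the shallowest library, 42 and 17 without late K12 replicate 1, 336 and 136 without late tnaA replicate 2, and 459 and 268 without late K12 replicate 3. With the replicate number as a block they were 21 and 25, and the lower count was 406 with DESeq2, 990 with the compared groups alone and 1200 over genes of at least 5 mean CPM.

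Camera called 6 further lists higher on K12, most of them with few called members. Of 32 proteasome genes 17 rose, with 24 adjusted over the list alone and a median of 0.21, among them the core subunit gene pbs-6 (0.29 ± 0.05). In the DNA replication and cell cycle list 7 of 30 rose, with 18 adjusted over the list alone and a median of 0.16, among them cye-1, which codes for cyclin E (0.25 ± 0.06). In the oxidative phosphorylation list 6 of 40 rose, with 11 adjusted over the list alone, among them the ATP synthase gene atp-2 (0.34 ± 0.07). Of 14 genes for mitochondrial chaperones and stress 5 rose, the same number adjusted over the list alone, among them hsp-60 (0.61 ± 0.10) and the prohibitin gene phb-2 (0.34 ± 0.06). Of 77 cytosolic ribosomal protein genes 4 rose and 2 fell, with 3 and 2 adjusted over the list alone, and the paralogs rpl-11.1 (0.28 ± 0.06) and rpl-11.2 (-0.35 ± 0.06) moved apart. Of 105 collagen genes 9 rose and 1 fell, also adjusted over the list alone, among them col-80 (2.85 ± 0.61). Camera called these 6 lists higher (adjusted p = 9.04e-16, 1.11e-09, 2.13e-06, 0.00427, 2.64e-09 and 0.0189). Adjusted p was 0.388 to 0.667 with an estimated correlation. Fry did not call oxidative phosphorylation, ribosomal proteins or collagens (adjusted p = 0.126, 0.194 and 0.442). The collagen call was lost without late tnaA replicate 2 and without late K12 replicate 3. All calls in these lists were lost without late tnaA replicate 3, and all but 1 collagen call without late K12 replicate 1. Without late tnaA replicate 2 rises numbered 4 for proteasome, 3 for oxidative phosphorylation and mitochondrial chaperones and 1 for collagens, and those of DNA replication and ribosomal genes were lost. Without late K12 replicate 3 they were 5 for proteasome and collagens and 2 for DNA replication, and those of ribosomal genes were lost. Collagen rises numbered 17 without late ahr-1 replicate 1 or 3, and ribosomal rises 12 and 15 without these and 2 without early K12 replicate 2. Of the 106 genes called under the naming rule, 10 held without late tnaA replicate 3, 21 without late K12 replicate 1, 47 without late tnaA replicate 2 and 62 without late K12 replicate 3.

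Camera called 4 lists lower on K12, each with few called members. Of 28 neuronal genes 3 were lower on K12, with 8 lower and 1 higher adjusted over the list alone and a median of -0.22, among them unc-10 and syd-2 of the presynaptic active zone (-0.44 ± 0.10 and -0.33 ± 0.07). Of 30 FMRFamide-like neuropeptide genes 2 were lower, with 1 adjusted over the list alone. Of 59 UDP-glucuronosyltransferase genes 6 were lower and 3 higher, with 10 and 5 adjusted over the list alone, among them ugt-31 (-0.85 ± 0.13). Of 36 genes of fatty acid synthesis and oxidation 6 were lower and 2 higher, with 10 and 3 adjusted over the list alone, among them the lysosomal lipase gene lipl-3 (-1.84 ± 0.35). Camera called these 4 lists lower (adjusted p = 2.92e-04, 0.0264, 0.0264 and 0.0189). Adjusted p was 0.365 to 0.572 with an estimated correlation. The calls of the peptide and glucuronosyltransferase lists were lost without late tnaA replicate 3 and without late K12 replicate 1, and that of the fatty acid list without late tnaA replicate 2. Fry did not call the peptide and fatty acid lists (adjusted p = 0.0532 and 0.118). Without late tnaA replicate 3 all calls of members in the 4 lists were lost, and without late K12 replicate 1 all but 1 fatty acid rise. Without late tnaA replicate 2 there were 1 neuronal and 2 glucuronosyltransferase falls left, with 1 fatty acid rise. Without late K12 replicate 3 the neuronal and peptide calls were lost and 1 fatty acid rise was left. Neuronal falls numbered 5 without early K12 replicate 3, and peptide falls 1 without early tnaA replicate 2 or 3 or early K12 replicate 2. The nuclear hormone receptor gene nhr-155 had 0.234 ± 0.0739 CPM on K12 and 7.82 ± 0.886 on tnaA (-5.0 ± 0.46, adjusted p = 0.001). The metallothionein gene mtl-2 fell from 73.5 ± 9.32 CPM on tnaA to 41.1 ± 0.435 on K12 (-0.85 ± 0.09), as did the saposin-like antimicrobial gene spp-1 (-1.51 ± 0.16), the ferritin gene ftn-1 (-1.45 ± 0.20), the lectin gene clec-47 (-1.74 ± 0.24) and nhr-136 (-1.33 ± 0.15). The drug efflux transporter gene pgp-1 was higher on K12, 38.8 ± 1.32 against 12 ± 1.14 CPM (1.64 ± 0.12, adjusted p = 4.46e-05), as were the lysozyme gene ilys-5 (1.90 ± 0.22), the cytochrome P450 gene cyp-13A5 (1.06 ± 0.10) and the lipase-like gene lips-11 (2.27 ± 0.30). Calls of nhr-155, nhr-136, spp-1, mtl-2, csr-1, pgp-1, ilys-5, cyp-13A5 and cyp-35C1 (-0.95 ± 0.13) held without any of the 11 libraries. Other named genes lost their call without late tnaA replicate 2 or 3 or late K12 replicate 1 or 3, which kept 47, 10, 21 and 62 of the 106.

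The largest rises on K12 follow, among called genes with a symbol, at least 5 CPM in the higher group and no overlap between libraries. The folate transporter gene folt-2 (4.00 ± 0.60) stood at 10.5 ± 6.74 CPM against 0.700 ± 0.322. The vitellogenin gene vit-3 (3.94 ± 0.77) stood at 180 ± 70.4 against 11.9 ± 1.08. The acyl-CoA dehydrogenase gene acdh-1 (3.63 ± 0.79) stood at 14.7 ± 14.1 against 1.18 ± 0.0818. The SD between the 2 K12 libraries was large for each. Of the 6 vitellogenin genes vit-3 and vit-4 (2.33 ± 0.50) rose, also adjusted over the list alone. The genes vit-1, vit-2, vit-5 and vit-6 were not called (1.06 ± 0.45, -0.21 ± 0.10, 0.17 ± 0.10 and -0.09 ± 0.10). Reads shared between paralogs leave the split among vit-1 to vit-5 uncertain, so also the rises of vit-3 and vit-4. The list was not called (camera adjusted p = 0.0974). All 4 of these late libraries mattered to such calls, since leaving out late tnaA replicate 2 or 3 or late K12 replicate 1 or 3 kept 47, 10, 21 or 62 of the 106 named calls.

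The remaining lists were not called by camera in this comparison. Among 129 C-type lectin genes 13 were higher and 4 lower, among 65 cytochrome P450 genes 5 and 6, and among 24 intestinal genes 2 and 4. Among 21 genes raised by DAF-16 there were 1 and 4, among 15 lowered by DAF-16 1 and 1, among 12 lysozyme genes 1 and 3, among 24 muscle genes 2 and 1, and among 10 genes of tryptophan and kynurenine metabolism 1 and 1, the lower one being tdo-2, which codes for tryptophan dioxygenase (-0.40 ± 0.12). Only lower calls were found for the HIF-1 pathway (4 of 11, with hif-1 at -0.23 ± 0.05) and the endoplasmic reticulum unfolded protein response (4 of 20, with atf-6 at -0.42 ± 0.09). The same held for antimicrobial peptides (3 of 32), insulin-like peptides (2 of 30), glutathione S-transferases (1 of 39) and the ahr-1 pathway (1 of 12, again hif-1). Of 17 genes of the PMK-1 and infection response 3 were higher. Adjusted over the list alone, higher and lower counts became 14 and 4 for lectins, 5 and 8 for cytochrome P450, 2 and 5 for intestinal genes and for genes raised by DAF-16, 1 and 2 for genes lowered by it, 2 and 4 for lysozymes, 4 and 3 for muscle, 3 and 0 for heat shock and 0 and 5 for the unfolded protein response. None of the 16 sperm, 16 early embryo, 25 larval cuticle or 13 heat shock genes was called by edgeR, where 2045 genes were higher and 1956 lower at an unadjusted p under 0.05. DESeq2 called 406 lower genes in all. The receptor gene ahr-1 (0.27 ± 0.44) and its partner aha-1 (-0.21 ± 0.08) were not called. The median, mean and test did not all agree in sign for the larval cuticle, heat shock and C-type lectin lists.

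**Figure D2:**
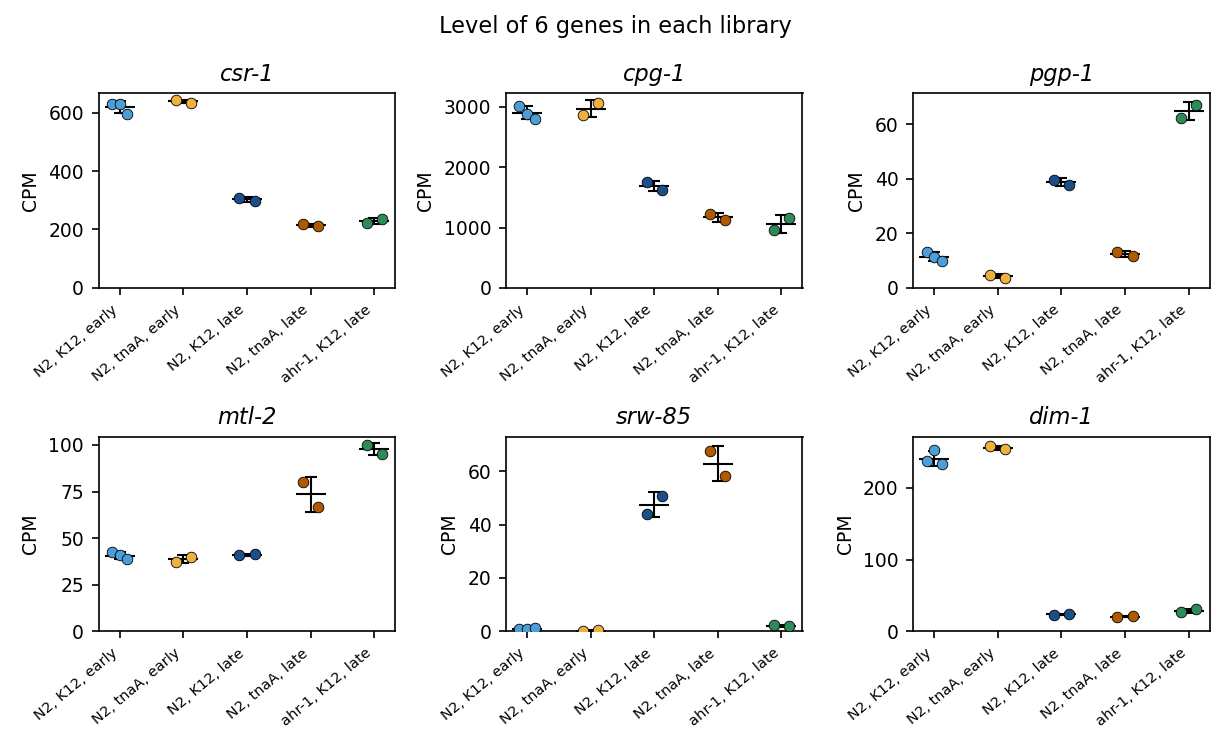
CPM of csr-1, cpg-1, pgp-1, mtl-2, srw-85 and dim-1 are plotted per library (points), with the mean and SD of each of the 5 groups. For csr-1 the late K12 mean is 303, the late tnaA mean 215 and the early K12 mean 619.

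In late ahr-1 mutants on K12, most genes of the germline, oogenesis, meiosis and ribosomal lists were lower than in N2, and 18 of 30 genes of the DNA replication list were higher. The list calls by camera that follow were all lost with an estimated correlation (adjusted p from 0.453 to 0.643). Reads outside genes made up 12.7% of the late ahr-1, about 12% of the late tnaA and 8.41% of the late K12 libraries, so this share differed along with both late comparisons and was not separated from them. The mutated gene itself had 19 and 14 reads in ahr-1 libraries, 56 and 35 in late K12, 44 and 17 in late tnaA, 7 and 3 in early tnaA, and 4, 13 and 13 in early K12. It stood at 1.31 ± 0.391 CPM in the mutant and 2.66 ± 0.767 in N2 (-1.03 ± 0.47, adjusted p = 0.130), so at this depth no change was detectable. The part of the gene that ia3 affects is not known here, so these counts are a weak check of the labels. Its partner aha-1 was not called (-0.10 ± 0.08, adjusted p = 0.410), nor were vit-2 (0.26 ± 0.10) and vit-6 (0.06 ± 0.10).

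Of 26 oogenesis and eggshell genes 20 fell and 2 rose in the mutant, the same numbers adjusted over the list alone, with a median of -0.39, among them cpg-1, at 1056 ± 147 CPM against 1689 ± 88.0 (-0.68 ± 0.08, adjusted p = 2.35e-04). Another was egg-3 (-0.48 ± 0.06). In the germline and P granule list 17 of 25 fell, with 18 adjusted over the list alone, among them csr-1 (-0.41 ± 0.06) and the RNA-binding protein gene car-1 (-0.66 ± 0.08). Of 31 meiosis genes 18 fell, with 20 falling and 1 rising adjusted over the list alone, among them zim-3 (-0.62 ± 0.07). Of 77 cytosolic ribosomal protein genes 49 fell and 1 rose, with 55 and 1 adjusted over the list alone and a median of -0.23, among them rps-4 (-0.45 ± 0.06, adjusted p = 4.27e-04). Of 105 collagen genes 20 fell and 3 rose, with 19 and 3 adjusted over the list alone and a median of -0.65, or -0.63 with a member at 0 reads at its bound. Of 13 heat shock genes 6 fell, with 6 falling and 1 rising adjusted over the list alone, among them hsp-70 (-0.84 ± 0.11), hsp-110 (-0.64 ± 0.06) and hsp-16.41 (-1.16 ± 0.13), which shares reads with its paralogs. Of 14 mitochondrial chaperone genes 6 fell, with 7 and 1 adjusted over the list alone, among them hsp-6 (-0.45 ± 0.06). The larval cuticle list had 2 rises and 2 falls among 25, also adjusted over the list alone, with mlt-10 at 1.08 ± 0.16 and ptr-4 at -1.24 ± 0.23. Camera called these 8 lists lower (adjusted p = 5.59e-08, 5.59e-08, 2.61e-07, 6.40e-19, 1.03e-04, 0.0161, 0.0223 and 0.0322). With an estimated correlation adjusted p was 0.453 for the first 7 and 0.643 for larval cuticle. The collagen call was lost without late ahr-1 replicate 1, and the larval cuticle call without late ahr-1 replicate 3. Called falls in the germline list numbered 6 without late K12 replicate 1 and 9 without late ahr-1 replicate 1, and in the ribosomal list 26 without late K12 replicate 1, 31 without late K12 replicate 3 and 31 without late ahr-1 replicate 1. Meiosis falls numbered 4 without late K12 replicate 1 and 5 without late ahr-1 replicate 1, and oogenesis falls 12 without late K12 replicate 1. Both oogenesis rises were lost without late K12 replicate 1 or 3, and 1 was left without late or early tnaA replicate 2, early tnaA replicate 3 or late ahr-1 replicate 1 or 3. Collagen falls numbered 12 without late K12 replicate 1, 10 without late K12 replicate 3, 9 (with 6 rises) without late ahr-1 replicate 1 and 31 without late ahr-1 replicate 3. Larval cuticle falls numbered 1 without late K12 replicate 1 or 3 or late ahr-1 replicate 1, 8 without early K12 replicate 1 and 4 without early K12 replicate 2 or 3. Fry did not call collagens or larval cuticle (adjusted p = 0.0713 and 0.371).

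Genes of DNA replication and the cell cycle rose in the mutant although those of the germline fell. In that list 18 of 30 rose and 2 fell, with 20 and 4 adjusted over the list alone and a median of 0.20, among them the ribonucleotide reductase gene rnr-2, at 1040 ± 65.1 CPM against 655 ± 20.6 (0.67 ± 0.06, adjusted p = 3.44e-05), the licensing factor gene cdt-1 (0.59 ± 0.06) and the helicase gene mcm-3 (0.32 ± 0.06). Of 20 genes of the endoplasmic reticulum unfolded protein response 11 rose and 2 fell, also adjusted over the list alone, among them the transcription factor gene xbp-1 (0.48 ± 0.06). Of 24 muscle genes 7 rose, with 9 adjusted over the list alone. Of 32 antimicrobial peptide genes 8 rose and 1 fell, with 10 and 1 adjusted over the list alone, among them cnc-2 (1.03 ± 0.12) and spp-1 (1.33 ± 0.16). Of 30 insulin-like peptide genes 2 rose, also adjusted over the list alone. Camera called these 5 lists higher (adjusted p = 7.32e-06, 0.0120, 0.00277, 0.00325 and 0.0280). Adjusted p was 0.453 to 0.459 with an estimated correlation. The muscle call was lost without late ahr-1 replicate 3, and that of insulin-like peptides without late K12 replicate 3 or late ahr-1 replicate 1. Called rises in DNA replication numbered 5 without late K12 replicate 1, 7 without late K12 replicate 3, 13 without late ahr-1 replicate 1 and 8 without late ahr-1 replicate 3. In the same order, rises in the unfolded protein response numbered 3, 5, 5 and 7. Muscle rises were 3 without late K12 replicate 1, 2 without late K12 replicate 3 and 2, beside 2 falls, without late ahr-1 replicate 3. Antimicrobial rises were 3 without late K12 replicate 1 and 4 without late ahr-1 replicate 1, and 3 antimicrobial genes fell without late ahr-1 replicate 3. Both insulin-like rises were lost without late K12 replicate 1 or late ahr-1 replicate 1, and 1 was left without late K12 replicate 3. The falls in DNA replication were lost without late K12 replicate 1 or late ahr-1 replicate 1, and those in the unfolded protein response without late K12 replicate 1, with 1 left without late K12 replicate 3 or late ahr-1 replicate 3. Fry did not call the muscle list (adjusted p = 0.0713).

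Sperm transcripts were scarce in late N2 libraries and rose in the mutant. Of 16 sperm genes 8 rose, with 11 adjusted over the list alone and a median of 2.47, or 2.44 with 2 members at 0 reads at their bounds. Camera called the list higher (adjusted p = 0.00297), which was lost at adjusted p = 0.586 with an estimated correlation, and fry did not call it (adjusted p = 0.164). The phosphatase gene gsp-3 had 1 read in late N2 on K12 and 158 in the mutant, a ratio of 211 with an interval of 37.3 to 8371. Likewise msd-4 had 1 and 115 reads (153, 27 to 6107) and ssq-4 had 3 and 263 (117, 39.6 to 570). The mean log2 CPM of the list was 1.56 and 1.75 in late ahr-1 replicates 1 and 3, -0.41 and -0.36 in late K12 replicates 1 and 3, and 0.10 and -0.39 in late tnaA replicates 2 and 3. It was also high in some early libraries, with 1.93 and 0.14 in early tnaA replicates 2 and 3 and 0.49, -0.29 and 1.83 in early K12 replicates 1, 2 and 3. Other rises with known roles in sperm were msp-59 (5.09 ± 1.23), which shares reads with other major sperm protein genes, and the Argonaute gene alg-4 (4.06 ± 1.07). Called sperm genes numbered 1 without late K12 replicate 1, 3 without late K12 replicate 3, and 5 without late ahr-1 replicate 1 or 3.

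The most significant single gene was the chemoreceptor-like gene srw-85, which fell from 47.4 ± 4.72 CPM in N2 to 2.05 ± 0.289 in the mutant (-4.53 ± 0.16, adjusted p = 6.54e-09). The fatty acid elongase genes elo-2 (-1.19 ± 0.08, adjusted p = 4.18e-06) and elo-5 (-1.98 ± 0.20, adjusted p = 8.65e-05) fell, as did folt-2 (-3.04 ± 0.52) and acdh-1 (-2.98 ± 0.72). The falls of folt-2 and acdh-1 rest on the same late K12 libraries as their rises against tnaA. Those libraries differed widely from each other for these genes. The cathepsin-like protease gene cpr-2 (3.55 ± 0.24), mtl-2, at 97.7 ± 3.33 CPM (1.25 ± 0.08, adjusted p = 4.13e-06), and the lysozyme gene ilys-3 (4.36 ± 0.54) rose. So did the DNase gene nuc-1 (0.77 ± 0.06), pgp-1 (0.74 ± 0.10), ftn-1 (1.43 ± 0.20), the peroxisomal thiolase gene daf-22 (0.71 ± 0.09) and the detoxification genes cyp-34A9 (2.00 ± 0.22), cyp-37B1 (2.23 ± 0.29), ugt-1 (2.06 ± 0.24) and ugt-17 (1.25 ± 0.11). In the ahr-1 pathway list 1 of 12 was called, the guanylate cyclase gene gcy-37, which fell (-0.95 ± 0.20) and lost its call without late K12 replicate 1 (adjusted p = 0.0518). Of the 138 genes called under the naming rule, 95 held without late K12 replicate 1, 111 without late K12 replicate 3, 110 without late ahr-1 replicate 1 and 123 without late ahr-1 replicate 3.

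This comparison asked what the receptor does in old worms on indole-producing bacteria. In all, 1855 genes were higher and 1840 lower in the mutant, 443 and 164 of them by at least 2-fold. With RLE size factors the split was 1616 and 2422, with library size only 2001 and 1847, and with DESeq2 1111 genes were higher. Without late K12 replicate 1 the counts were 670 and 740, without late K12 replicate 3 1097 and 1209, and without late ahr-1 replicate 1 1016 and 963. The lists not called had 5 rises among 16 early embryo genes, 7 falls and 2 rises among 28 neuronal genes, 5 rises and 1 fall among 30 FMRFamide-like peptide genes, 5 falls among 32 proteasome genes and 9 falls and 2 rises among 40 oxidative phosphorylation genes. Others had 16 rises and 6 falls among 129 C-type lectin genes (a median of 0.02, which RLE size factors turned to -0.01), 9 falls and 7 rises among 36 fatty acid genes and 7 rises and 3 falls among 21 genes raised by DAF-16. Of 65 cytochrome P450 genes 7 rose and 8 fell, of 59 UDP-glucuronosyltransferase genes 8 rose and 7 fell, and of 39 glutathione S-transferase genes 1 rose and 6 fell. Of 24 intestinal genes 3 rose and 3 fell, of 12 lysozyme genes 2 rose and 2 fell, of 15 genes lowered by DAF-16 2 rose and 2 fell, of 11 HIF-1 pathway genes 1 rose and 2 fell, and of 10 tryptophan and 17 PMK-1 genes 1 each fell. Adjusted over the list alone, rises and falls became 12 and 4 for lectins, 8 and 11 for fatty acid genes, 8 and 3 for genes raised by DAF-16, 7 and 7 for cytochrome P450, 1 and 3 for glutathione S-transferases, 5 and 4 for intestinal genes and 2 and 5 for lysozymes. None of the 6 vitellogenin genes was called by edgeR, where 2764 genes were higher and 2811 lower at an unadjusted p under 0.05, against 1111 higher in DESeq2. The median, mean and test did not all agree in sign for the intestinal, lysozyme and DAF-16-lowered lists.

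**Figure D3:**
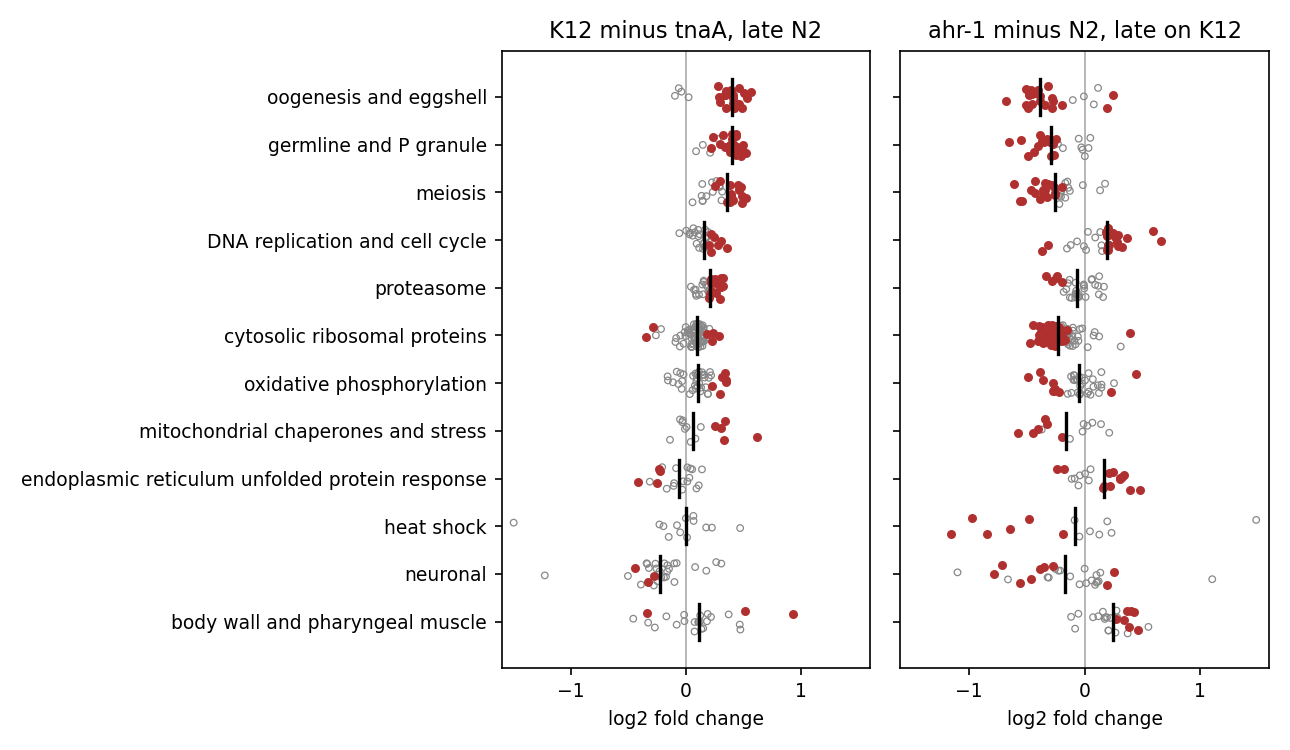
Log2 fold changes of the members of 12 gene lists are plotted for late K12 minus tnaA and for late ahr-1 minus N2, with called members in red and list medians as black bars. The median of the oogenesis list is 0.40 in the first and -0.39 in the second comparison, and that of the ribosomal list 0.10 and -0.23.

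Ageing on K12 lowered yolk, oocyte, muscle, ribosomal and proteasome transcripts and raised those of larval cuticle and neurons. All 6 vitellogenin genes fell, with vit-2 at 5243 CPM in late and 26682 in early worms (-2.35 ± 0.10), vit-5 at 1938 and 14023 (-2.86 ± 0.10) and vit-6 at 5294 and 23603 (-2.16 ± 0.10). The others were vit-1 at -4.85 ± 0.48, vit-3 at -4.69 ± 0.66 and vit-4 at -4.30 ± 0.49. Reads shared between paralogs leave the split among vit-1 to vit-5 uncertain. All 24 muscle genes fell, with a median of -2.49, among them dim-1 (-3.33 ± 0.07, adjusted p = 2.10e-12), the troponin C gene pat-10 (-3.67 ± 0.09), the tropomyosin gene lev-11 (-2.38 ± 0.06) and the myosin light chain gene mlc-1 (-3.75 ± 0.10). Of 26 oogenesis and eggshell genes 23 fell and 3 rose, with egg-3 at -1.07 ± 0.06. Of 25 germline genes 21 fell, with csr-1 at 303 CPM in late and 619 in early worms (-1.03 ± 0.05, adjusted p = 1.05e-09). Of 25 larval cuticle and moulting genes 20 rose and 1 fell, with a median of 1.75, among them the fibrillin-like gene fbn-1, at 207 ± 24.9 CPM against 16.8 ± 8.29 (3.61 ± 0.22, adjusted p = 6.35e-09), and the apical matrix gene noah-1 (3.00 ± 0.20).

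Of 28 neuronal genes 20 rose and 4 fell, with a median of 0.88, among them the neurexin gene nrx-1 (3.04 ± 0.11) and the synaptic vesicle priming gene unc-13 (1.74 ± 0.08). Falls were found for 74 of 77 ribosomal protein genes (3 rose, and rps-24 stood at 940 CPM against 1875, -1.0 ± 0.05), all 32 proteasome genes (rpt-4, -1.07 ± 0.05), all 40 oxidative phosphorylation genes, 28 of 30 DNA replication genes, and 24 of 31 meiosis genes (3 rose). Genes also fell in the intestinal list (20 of 24, 3 rose), among them the proton pump gene vha-6 (-3.16 ± 0.10). So did 11 of 15 genes lowered by DAF-16 (2 rose), 11 of 14 mitochondrial chaperone genes (2 rose), 69 of 129 C-type lectin genes (23 rose) and 7 of 10 tryptophan and kynurenine genes (1 rose), among them haao-1 (-3.54 ± 0.15). Of 30 insulin-like peptide genes 13 rose and 4 fell, with ins-2 at 4.99 ± 0.40, and the falls were fewer without late K12 replicate 3. Of 21 genes raised by DAF-16 12 rose and 3 fell, among them the cyclin-dependent kinase inhibitor gene cki-1 (3.83 ± 0.13) and the linker histone gene hil-1 (3.30 ± 0.12). Camera called these 18 lists (adjusted p from 7.97e-17 for ribosomal proteins to 0.0424 for insulin-like peptides). Adjusted p was 0.340 to 0.436 with an estimated correlation. Late K12 replicate 1 was needed for the calls of insulin-like peptides, C-type lectins and tryptophan genes, and late K12 replicate 3 for those of tryptophan genes and genes raised by DAF-16. The tryptophan call was also lost without late tnaA replicate 3, early tnaA replicate 2 or early tnaA replicate 3, and the insulin-like call without early K12 replicate 2 or 3. Adjusted over the list alone, the counts differed for germline (23 falls), meiosis (26) and insulin-like peptides (3 falls). With library size only, the medians turned from -0.40 to 0.02 for meiosis, from -0.42 to 0.00 for DNA replication and from -0.34 to 0.08 for mitochondrial chaperones.

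Single genes with large rises on K12 included the neuronal immunoglobulin gene zig-4, at 93.0 CPM against 1.68 (5.78 ± 0.12, adjusted p = 1.96e-12), the cuticlin-like gene cutl-8 (5.95 ± 0.17), srw-85 (5.69 ± 0.16), the neuropeptide gene nlp-39 (6.77 ± 0.30), and gcy-37 (5.36 ± 0.28). Metabolic and immune genes among them were the acyl-CoA synthetase gene acs-2 (4.13 ± 0.13), the fatty acid synthase gene fasn-1, at 1202 CPM against 256 (2.23 ± 0.07), clec-266 (4.35 ± 0.18) and lys-3 (5.63 ± 0.35). Early K12 libraries had 0 reads of the antimicrobial gene cnc-6 and the receptor gene str-31, which were at least 84.5-fold and 64-fold higher in late worms. The collagen genes col-139 (-8.01 ± 0.27) and col-129 (-7.84 ± 0.24), gst-13 (-3.75 ± 0.09), ilys-5 (-4.14 ± 0.18) and nlp-24 (-3.27 ± 0.10) fell. The sperm gene msp-81 had 1 read in late worms, a ratio of early to late of 271 with an interval of 48.2 to 10723. Early K12 libraries stood apart on the sperm list, with a mean log2 CPM of 0.49, -0.29 and 1.83 in replicates 1, 2 and 3. The receptor gene ahr-1 rose from few reads (1.72 ± 0.44, adjusted p = 0.00334), a call lost without late K12 replicate 1, where adjusted p was 0.0508, and aha-1 rose by 0.61 ± 0.07.

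This comparison asked what ageing changes on the indole-producing strain. Of the genes tested, 4974 were higher and 5553 lower in late worms, 3180 and 2065 of them by at least 2-fold. With library size only the median change of all genes moved up by 0.42, and on tnaA by 0.47. Then 7755 genes were higher and 3032 lower on K12, and 5356 and 5145 with RLE size factors, so the changes given are relative to the TMM scaling. The lists not called were cytochrome P450 (24 rose and 22 fell among 65, a median of -0.01 that became 0.41 with library size only), UDP-glucuronosyltransferases (15 and 32 of 59), glutathione S-transferases (10 and 16 of 39, a median of -0.36 that became 0.05), and lysozymes (3 and 6 of 12). They were also antimicrobial peptides (9 and 14 of 32, -0.20 to 0.21), the PMK-1 response (5 and 9 of 17), fatty acid genes (8 and 16 of 36, -0.24 to 0.18), and the HIF-1 pathway (4 and 3 of 11). The others were the ahr-1 pathway (9 and 1 of 12), FMRFamide-like peptides (9 and 4 of 30), heat shock (3 and 8 of 13, -0.28 to 0.14), the unfolded protein response (6 and 7 of 20), collagens (24 and 45 of 105), sperm (3 and 9 of 16) and early embryo genes (3 and 7 of 16). Sperm falls numbered 5 without early K12 replicate 3. When each library was left out in turn, the sperm median ran from -2.55 to -1.07 and the early embryo median from -0.793 to -0.319. The median, mean and test did not all agree in sign for the cytochrome P450 and antimicrobial lists.

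Ageing on tnaA went the same way for the same groups. All 6 vitellogenin genes fell, with a median of -4.48 and vit-3 at 11.9 CPM in late and 4609 in early worms (-8.61 ± 0.86). All 24 muscle genes fell (median -2.49, dim-1 at -3.64 ± 0.08), and 20 of 25 larval cuticle genes rose and 1 fell (median 3.2, or 3.08 with 2 members at 0 reads at their bounds, fbn-1 at 4.97 ± 0.28). Of 28 neuronal genes 23 rose and 3 fell, with nrx-1 at 3.92 ± 0.13. Falls were found for 23 of 26 oogenesis genes (3 rose, median -1.39, egg-3 at -1.49 ± 0.06) and 24 of 25 germline genes (median -0.96, csr-1 at -1.57 ± 0.06). They were also found for 28 of 31 meiosis, 27 of 30 DNA replication, 39 of 40 oxidative phosphorylation, 72 of 77 ribosomal (3 rose), all 32 proteasome, 19 of 24 intestinal, 12 of 15 DAF-16-lowered and 10 of 14 mitochondrial chaperone genes, where the median turned from -0.47 to 0.01 with library size only. Of 30 insulin-like peptide genes 16 rose and 3 fell. Camera called these 15 lists, the highest adjusted p being 0.0393 for insulin-like peptides. Adjusted p was 0.387 to 0.403 with an estimated correlation. The insulin-like call was lost without early tnaA replicate 2 or 3. Adjusted over the list alone, meiosis had 30 falls and the other counts were the same. Among the named genes the largest falls were folt-2, at 0.700 CPM against 397 (-9.26 ± 0.37), acdh-1, at 1.18 against 711 (-9.24 ± 0.55), col-20 (-9.25 ± 0.70) and col-93 (-9.18 ± 0.65). The gene nhr-155, with 0 reads in early worms on tnaA, was at least 64.1-fold higher in late ones, hmg-6 at least 76.7-fold and ins-20 at least 45.9-fold.

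On tnaA 5394 genes were higher and 5498 lower in late worms, 3831 and 2237 of them by at least 2-fold, with library size only 7848 and 3140, and with RLE size factors 5618 and 5299. The gene ahr-1 rose (2.45 ± 0.58, adjusted p = 0.00166), as did aha-1 (0.82 ± 0.08). The lists called on K12 but not on tnaA were those raised by DAF-16 (13 rose and 5 fell of 21, adjusted p = 0.0656), C-type lectins (23 rose and 50 fell of 129, adjusted p = 0.0795) and tryptophan and kynurenine genes (3 rose and 7 fell of 10, adjusted p = 0.128), and the test of the difference, given with the difference of ageing, called none of these 3. The other lists were not called. The median, mean and test did not all agree in sign for the early embryo, lysozyme and antimicrobial lists. The medians of the heat shock (-0.40 to 0.08), glutathione S-transferase (-0.23 to 0.24), antimicrobial (-0.23 to 0.24), fatty acid (-0.08 to 0.39) and UDP-glucuronosyltransferase (-0.34 to 0.14) lists turned with library size only.

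**Figure D4:**
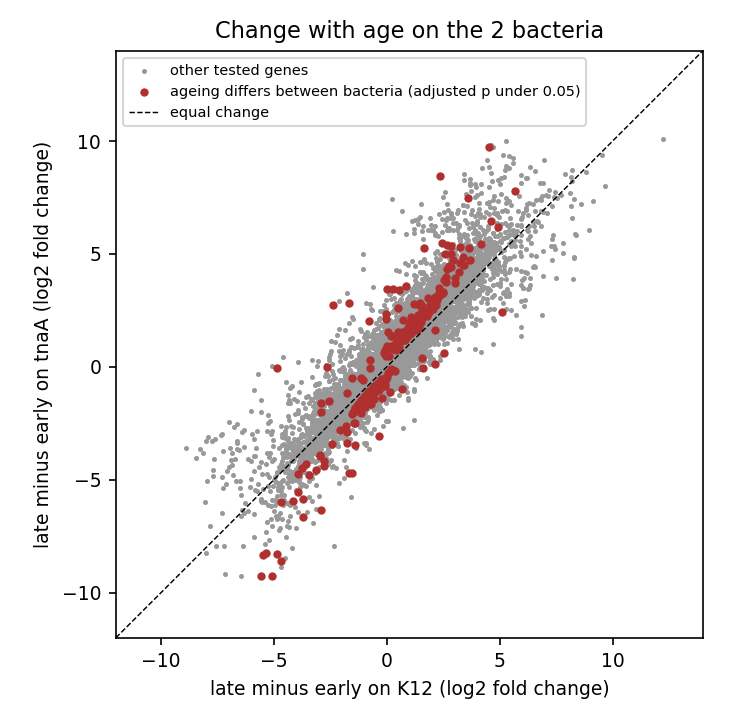
Each point is a gene, with its log2 fold change of late against early worms on K12 and on tnaA, red where the difference between both changes was called, and the dashed line marks equal change. Across 12828 genes r was 0.959, and 364 genes are red.

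Few genes differed between both bacteria in early worms, and 3 of the 8 lower on K12 were collagens. The collagen genes col-139, at 70.8 CPM on K12 and 173 on tnaA (-1.29 ± 0.11, adjusted p = 1.80e-04), col-129 (-1.21 ± 0.10) and col-81 (-1.18 ± 0.13) were lower on K12, as was F08G5.6 of the PMK-1 and infection response list (-1.69 ± 0.23). The transporter gene pgp-1 was higher, 11.5 ± 1.72 CPM against 4.24 ± 0.690 (1.43 ± 0.16, adjusted p = 0.00297), and so was pqn-32 (3.47 ± 0.51, adjusted p = 0.0265). Camera called larval cuticle higher (16 of 25 adjusted over the list alone, median 1.27, adjusted p = 2.33e-09) and 7 lists lower, namely muscle (median -0.14, adjusted p = 3.08e-09), heat shock (4.82e-07), genes raised by DAF-16 (0.00442), glutathione S-transferases (0.0127), the PMK-1 response (1 of 17 called, adjusted p = 0.00163), oxidative phosphorylation (8.75e-07) and ribosomal proteins (2.69e-09). With an estimated correlation adjusted p = 0.514 for the first 6 of these 8 and 0.891 for the last 2. Libraries stood apart on the larval cuticle list, with a mean log2 CPM of 3.38 and 2.93 in early K12 replicates 2 and 3 but 1.77 in early K12 replicate 1, against 1.80 and 1.90 in early tnaA replicates 2 and 3. Its median was 0.84 and 0.81 without early K12 replicate 2 or 3 and 1.62 without early K12 replicate 1. So the rise on K12 came from 2 of the 3 libraries. Without early tnaA replicate 3 the calls of the DAF-16, glutathione S-transferase, PMK-1, oxidative phosphorylation and ribosomal lists were lost, and without early K12 replicate 3 that of glutathione S-transferases. Fry called 0 lists, and pgp-1 lost its call without early tnaA replicate 3.

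This comparison asked whether young adults already differ by bacterial strain. In edgeR 2 genes were higher and 8 lower on K12, with 650 and 493 at an unadjusted p under 0.05, while DESeq2 called 47 and 42. The counts were 187 and 18 without early K12 replicate 1, 1 and 4 without early K12 replicate 2, and 8 and 35 without early K12 replicate 3. They were 1 and 14 without early tnaA replicate 2, 0 and 4 without early tnaA replicate 3, 1 and 4 without late tnaA replicate 2 or 3, and 4 and 10 without late ahr-1 replicate 1 or 3. With the compared groups alone they were 0 and 0. With no filter on low counts they were 274 and 171. The vitellogenin genes, ahr-1 and aha-1 were not called. The median, mean and test did not all agree in sign for the insulin-like peptide, intestinal, unfolded protein response, cytochrome P450 and UDP-glucuronosyltransferase lists.

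The change with age itself differed between the bacteria for germline genes, which fell less on K12 than on tnaA. The difference (ageing on K12 minus ageing on tnaA) was above 0 and called for 13 of 25 germline genes (23 adjusted over the list alone, median 0.39), among them csr-1 (0.54 ± 0.07). It was so as well for 9 of 26 oogenesis genes (22 adjusted over the list alone, median 0.39) and 5 of 31 meiosis genes (19, median 0.32), among them syp-2 (0.56 ± 0.10). It was so for 2 of 32 proteasome genes (23, median 0.23). It was below 0 for the larval cuticle list, with 1 member called (14 adjusted over the list alone, median -1.36), and for neuronal genes, with 1 member called, nrx-1 (-0.88 ± 0.19). Camera called these 6 lists (adjusted p = 5.61e-20, 8.58e-16, 2.55e-13, 1.12e-15, 2.57e-05 and 0.00116). With an estimated correlation all 6 calls were lost, at adjusted p = 0.449 for larval cuticle and 0.389 for the others, and fry called 0 lists of the 33. Above 0 it also called DNA replication, muscle, heat shock, mitochondrial chaperones, oxidative phosphorylation, ribosomal proteins and the PMK-1 response. Below 0 it also called the HIF-1 pathway (adjusted p = 0.0258). With an estimated correlation adjusted p ran from 0.389 to 0.505 for these lists, so none was called. Called germline, oogenesis and meiosis genes numbered at most 1 per list without any single one of late tnaA replicates 2 and 3, late K12 replicates 1 and 3, early tnaA replicates 2 and 3, and early K12 replicates 2 and 3. The proteasome calls were lost without any of these 8. Without late ahr-1 replicate 1 or 3 there were 18 oogenesis and 9 proteasome calls, with 10 and 11 for meiosis. Larval cuticle calls numbered 4 without late ahr-1 replicate 1 or 3 and 15 without early K12 replicate 1. The HIF-1 call was lost without late tnaA replicate 3, late K12 replicate 1, early tnaA replicate 2 or late ahr-1 replicate 1, the PMK-1 call without late tnaA replicate 2, and the heat shock call without late K12 replicate 3. The larval cuticle median ran from -1.69 to -0.976 when each library was left out in turn, and early K12 libraries stood apart from each other on this list.

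In all, 217 genes had a difference above 0 and 147 below 0, and at an unadjusted p under 0.05 there were 1639 and 1577. The counts were 2 and 1 without late tnaA replicate 2, 3 and 4 without late tnaA replicate 3, 24 and 13 without late K12 replicate 1, 11 and 11 without late K12 replicate 3, 21 and 9 without early tnaA replicate 2, and 2 and 3 without early tnaA replicate 3. They were 289 and 429 without early K12 replicate 1, 13 and 7 without early K12 replicate 2, 47 and 43 without early K12 replicate 3, 448 and 286 without late ahr-1 replicate 1, and 484 and 264 without late ahr-1 replicate 3. With the replicate number as a block they were 4 and 6, with DESeq2 614 and 215, and with RLE size factors 425 and 185. Further counts were about 120 and 190 with library size only, 689 and 634 with no filter on low counts, 397 and 433 over genes of at least 5 mean CPM, and 909 and 335 with the compared groups alone. Signs of the median, mean and test did not all agree for the sperm, collagen, glutathione S-transferase and lysozyme lists. Of the 217 and 147 genes, 208 and 95 were also called, in the same direction, in late K12 against tnaA. Both tests use the same late libraries, so most of these calls restate the late difference.

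Across 12828 genes, the changes with age on K12 and on tnaA correlated at r = 0.959 (Spearman's rho 0.953), with 92.5% of genes of the same sign and a ratio of SDs, K12 over tnaA, of 0.868. Both comparisons called 4554 genes higher and 4970 lower, and 3 in each opposite direction. The late change on tnaA (tnaA minus K12) correlated with ageing on K12 at r = 0.273 (rho 0.397). Sharing the late K12 libraries pulls this r down, to a mean of -0.512 (-0.533 to -0.482) in simulations where no gene changed. With real changes the pull on r is smaller, as the covariance was 0.135 against a simulated -0.0265. Of the 886 genes lower on tnaA than on K12 in late worms 790 also fell with age on K12, where independence would give 325, and of the 646 higher 494 rose with age (212), against 27 and 91 in opposite directions. These counts shared the late K12 libraries. With late K12 replicate 1 as the control of 1 comparison and replicate 3 as that of the other, r was 0.282 either way round. The share of reads outside genes rose along both changes. It was 6.14 to 7.19% in early K12 libraries and 8.56% and 8.27% in late K12 replicates 1 and 3. In late tnaA replicates 2 and 3 it was 9.26% and 14.8%. The split does not remove this, so the correlation and overlaps cannot tell older-looking worms on tnaA from a difference in library quality. Without late tnaA replicate 3 the late comparison called 10 and 15 genes, without late K12 replicate 1 42 and 17, without late tnaA replicate 2 336 and 136 and without late K12 replicate 3 459 and 268.

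The ahr-1 change correlated with the late tnaA change at r = 0.420 (rho 0.315), and r was 0.230 without late tnaA replicate 2. Simulations in which no gene changed gave a mean r of 0.467 (0.438 to 0.491) from the shared K12 libraries alone. Noise made up all variance there, so that value overstates what sharing gives here. Thus r alone does not decide whether a change is shared. The covariance of 0.0831 exceeded the simulated 0.0268, or 0.0320 with the larger noise. Of genes lower on tnaA 507 were also lower in ahr-1 mutants, where independence would give 108, and of genes higher on tnaA 249 were higher in the mutant (79.2), against 20 and 81 in opposite directions. The late comparison called 10 and 15 genes without late tnaA replicate 3, 42 and 17 without late K12 replicate 1, 336 and 136 without late tnaA replicate 2 and 459 and 268 without late K12 replicate 3. For ahr-1 the counts were 670 and 740 without late K12 replicate 1, 1097 and 1209 without late K12 replicate 3 and 1016 and 963 without late ahr-1 replicate 1. Splitting the late K12 libraries between both comparisons, chosen after r had been seen, gave r = 0.264 with replicate 3 as the tnaA control and 0.318 with replicate 1. In the second split 102 genes were higher in both where independence would give 16.3 and 171 lower in both (26.7), against 37 in opposite directions (42.5). In the first only 15 and 41 genes were called on tnaA, with 4 higher in both (1.17), 17 lower in both (3.45) and 13 opposite (4.47). A lone control library was assumed to vary like the other groups. The raised share of reads outside genes in both late tnaA and ahr-1 libraries is not removed by the split. The ahr-1 change was nearly uncorrelated with ageing on tnaA (r = -0.0863, rho 0.0541), a pair that shares no libraries. There r was 0.0448 without late ahr-1 replicate 3 and 0.103 over genes of at least 5 mean CPM. Yet called genes overlapped, with 1181 lower and 835 higher in both, where independence would give 668 and 661. In opposite directions there were 577 and 500 genes (674 and 656). Late and early differences between the bacteria were nearly uncorrelated too (r = -0.0130, rho -0.0773). These 5 correlations are descriptions across genes, which are not independent replicates, and carry no test.

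The tables deposited by the authors listed 1380 genes for late K12 against tnaA, 968 higher and 412 lower on K12, of which 1378 were matched and all had the same sign here, and 1065 were called here too. For ahr-1 they listed 2071 genes, 1140 higher and 931 lower in the mutant, of which 2069 were matched, all of the same sign, and 1986 were called here too. Fold changes correlated at r = 0.963 and 0.782 over the listed genes, with SDs 0.760 and 0.402 times those of the edgeR values. The changes in the deposited tables were close to these for abundant genes such as csr-1 (0.52 there, 0.50 here) and far smaller for gsp-3, with 1 read in late K12 libraries (1.81 there, 7.31 here).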

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

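In this part, the test of a larger share of germline tissue, the reading of the male soma test, and the fits with thinned libraries or with library size only were chosen after the results had been seen. The other tests had bounds written before the values they measure were seen.

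Ageing changed genes differently on K12 and tnaA by the test of the difference itself, with 217 genes above 0 and 147 below 0. Of these, 208 and 95 were already called, in the same direction, in late K12 against tnaA with the same late libraries. So most of them are not a separate finding. The named genes furthest above 0 were folt-2 (4.19 ± 0.63), vit-3 (3.92 ± 0.92), acdh-1 (3.67 ± 0.85), asp-17 (3.15 ± 0.57) and col-80 (2.93 ± 0.68). Reads shared with paralogs leave the value of vit-3 uncertain. The SD between the late K12 libraries was large for folt-2, vit-3 and acdh-1. Those furthest below were lipl-6 (-2.74 ± 0.66), dpy-1 (-2.37 ± 0.47), nphp-1 (-2.15 ± 0.50), srw-85 (-2.09 ± 0.48) and mlt-11 (-1.68 ± 0.39). The value of srw-85 leans on early libraries with few reads, at 0.233 and 0.327 CPM on tnaA and 0.722 to 1.09 on K12. Its late levels were 67.4 and 58.1 CPM on tnaA and 44.1 and 50.7 on K12. Of the 54 named genes with a called difference, 54 kept their call without early K12 replicate 1 and without late ahr-1 replicate 1 or 3, and 15 without early K12 replicate 3. It was 11 without late K12 replicate 1, 8 without early tnaA replicate 2, 6 without early K12 replicate 2, 5 without late K12 replicate 3, 3 without late tnaA replicate 3, 1 without early tnaA replicate 3 and 0 without late tnaA replicate 2, where edgeR called 2 and 1 genes in all.

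Sperm genes rose in late ahr-1 libraries, with 8 of 16 called, of which 1 was called without late K12 replicate 1, 3 without late K12 replicate 3 and 5 without late ahr-1 replicate 1 or 3. Fewer reads in the mutant libraries would lower the number of sperm reads there, not raise it. So thinning all libraries to the lowest total, which left 7 of the 8 called, was no strong test of this explanation. Males among the mutant worms cannot be told apart from a change in hermaphrodites: summed male soma counts were 0.675 times those of N2 (95% interval 0.555 to 0.818, 162 against 320 reads over 8 genes), below the bound set beforehand, but the bound was a wrong one, because the 320 reads already present in late N2 would hide a small share of males. The male soma list, of which 0 genes are in another list, was led by try-5 (2.79 CPM in the mutant, 4.00 in N2) and cwp-4 (1.26 and 1.59), and 7 of its 8 genes had reads in early K12 worms though 0 reached 1 CPM there. Sperm left in hermaphrodites by the mutation itself stays open and untested, as early K12 replicate 3 and early tnaA replicate 2 held as many sperm transcripts (mean log2 CPM of the list 1.83 and 1.93) as the mutant.

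Larval cuticle genes rose with age, with 20 of 25 called on K12 and 20 of 25 on tnaA. With library size only the medians were 2.17 and 3.68. That scaling moved the median of all genes up too, by 0.42 and 0.47. TMM thus lowered these changes, so this fit could not have shown a rise made by TMM. Embryos or larvae in or among the late worms may contribute, because the embryonic patterning list rose too, with medians of 1.63 on K12 (quartiles 0.69 to 2.83) and 2.54 on tnaA (1.22 to 3.19). Its most abundant genes in late K12 worms, in order of level and not of rise, were lin-26 (155 CPM in late and 111 in early K12 worms), ceh-43 (97.2 and 7.19) and vab-3 (82.8 and 4.27). That list has 0 genes in other lists, but 15 of its 19 genes stood at 1 CPM or more in early worms as well. The neuronal list also rose with age on both bacteria, so a rise of the patterning list could come without embryos. The early embryo list, which was not called, went the other way. When each library was left out in turn, its median ran from -0.793 to -0.319 on K12 and from -0.593 to -0.208 on tnaA. The patterning and early embryo lists together do not settle whether embryos or larvae contributed. Re-expression in the aged hypodermis is a candidate the design does not test.

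Oogenesis, germline and meiosis genes stood higher in late worms on K12 than on tnaA, with 60 of 82 called, a median of 0.38 and 1 called without late tnaA replicate 3. Of the germline list alone, 21 of 25 were called, 1 without late K12 replicate 1, 14 without late tnaA replicate 2 and 18 without late K12 replicate 3. The shallow late tnaA replicate 3 is not the whole cause, since the median was 0.36 without it. A larger share of germline tissue in worms on K12 would lower all other tissues alike. Medians of somatic lists moved apart instead, with 0.12 for muscle (quartiles -0.03 to 0.20) and -0.22 for neuronal genes (-0.32 to -0.14). They were -0.13 for intestinal and 0.23 for collagen genes. So somatic genes changed in other ways too, which cannot tell how much of the germline rise came from tissue share. Tissue share, lower library quality on tnaA and an effect of indole within germ cells stay open and untested. Reads outside genes made up 14.8% and 9.26% of late tnaA replicates 3 and 2, against a mean of 8.41% on K12.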

How the results depend on the processing

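In this part, library size only, thinning and the split of the late K12 libraries were chosen after the results had been seen. All other alternatives were planned. Leaving out each library in turn gave 10 to 1121 genes higher and 15 to 746 lower for late K12 against tnaA, 670 to 2030 and 740 to 1911 for ahr-1, and 4332 to 5046 and 4799 to 5610 for ageing on K12. They were 4835 to 5430 and 5056 to 5572 for ageing on tnaA, 0 to 187 and 4 to 35 for early K12 against tnaA, and 2 to 484 and 1 to 429 for the difference. Where it left a group with 1 library, that library was assumed to vary like the other groups. The correlations ranged over 0.939 to 0.960 for both ageing changes, -0.184 to 0.0448 for ahr-1 with ageing on tnaA, -0.140 to 0.110 for late with early, 0.230 to 0.492 for ahr-1 with the tnaA change, and 0.202 to 0.328 for the late tnaA change with ageing on K12. The lowest counts for late K12 against tnaA came without late tnaA replicate 3 and those for ahr-1 without late K12 replicate 1.

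With a replicate block, late K12 against tnaA had 21 higher and 25 lower, early 1 and 5, the difference 4 and 6, and late with early r = 0.0947. Differences between like-numbered libraries correlated at -0.532 (early K12 with early tnaA) to 0.196. Late K12 and late tnaA share only replicate number 3, so this could not be looked at for them. Whether the numbers pair the libraries stays open. With DESeq2, late K12 against tnaA had 406 lower, ahr-1 1111 higher, early 47 and 42, and the difference 614 higher. With no filter, early had 274 and 171 and the difference 689 and 634. With a mean of at least 5 CPM, late K12 against tnaA had 1200 lower, the difference 397 and 433, and r was 0.975 (both ageing changes), 0.103 (ahr-1 with ageing on tnaA, turned from -0.0863), -0.107 (late with early) and 0.456 (late tnaA with ageing on K12). With the compared groups alone, late K12 against tnaA had 990 lower, early 0 and 0 by edgeR (650 and 493 at an unadjusted p under 0.05 in the full fit, 47 and 42 by DESeq2) and the difference 909 and 335. With RLE size factors the difference had 425 higher. With library size only, ageing on K12 had 7755 and 3032, ageing on tnaA 3140 lower, early 1 and 5, the difference 1.2e+02 higher (rounded), and dnj-12 and cah-4 on K12 turned from -0.42 to 0.00446 and from -0.36 to 0.0628. Thinned, early had 1 and 5. With a prior count of 0.5, r was 0.953 for both ageing changes and 0.197 for the late tnaA change with ageing on K12. Without late ahr-1 replicate 3, r for ahr-1 with ageing on tnaA turned to 0.0448. With each late K12 library given to 1 comparison only, r was 0.264 and 0.318 for ahr-1 with the tnaA change and 0.282 both ways for the late tnaA change with ageing on K12. The cause of these moves was not tested.

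Of values for named genes, 153 were weaker and 479 alike with the replicate block, 25 weaker and 567 alike with DESeq2, 29 and 603 when thinned, 15 and 614 with library size only, and 3 and 629 with RLE size factors. Depth limits what can be seen of genes with few reads, since 1 read is up to 0.103 CPM.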

Other observations

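All families in this part were chosen after the data had been seen, by name prefix, and tested among 120 families with at least 10 measured members. In late ahr-1 mutants 24 of 28 major sperm protein genes (msp) rose, with a median of 5.6, though their reads cannot be told apart, and so did 25 of 97 F-box genes (fbxb), 11 of 19 Skp1-related genes (skr, 2 fell), 14 of 48 transthyretin-related genes (ttr, 1 fell) and 8 of 31 histone genes (his, 2 fell), while 13 of 39 and 15 of 27 mitochondrial ribosomal protein genes (mrpl and mrps) fell. Camera adjusted p for msp, fbxb, skr, ttr, his and mrps was 4.11e-04, 1.63e-04, 0.00229, 2.69e-04, 0.00579 and 5.14e-06, and adjusted p was 0.533 to 0.907 with an estimated correlation. Without late K12 replicate 1 the comparison called 670 higher and 740 lower genes, without late K12 replicate 3 1097 and 1209, and without late ahr-1 replicate 1 1016 and 963. In late worms 26 of 197 nuclear hormone receptor genes (nhr) were lower on K12 than on tnaA (median -0.26, adjusted p = 1.04e-08, and adjusted p = 0.509 with an estimated correlation), a comparison that held 10 higher and 15 lower genes without late tnaA replicate 3, 42 and 17 without late K12 replicate 1, 336 and 136 without late tnaA replicate 2 and 459 and 268 without late K12 replicate 3.

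With age, 20 of 25 cuticlin-like genes (cutl) rose on K12 and 22 on tnaA, with medians of 3.21 and 4.27, as did 10 of 11 ciliary dyf genes on each, 18 and 17 of 24 guanylate cyclase genes (gcy), 13 and 14 of 17 chemoreceptor genes (str) and 108 and 123 of 197 nhr genes. All 19 vacuolar ATPase genes (vha) fell on both bacteria, with medians of -1.0 and -1.12, and 12 of 13 aspartyl protease genes (asp) fell on both, with medians of -2.52 and -2.56. Camera adjusted p for cutl was 9.02e-06 on K12 and 2.75e-05 on tnaA, and adjusted p was 0.382 and 0.344 with an estimated correlation. These medians kept their sign with RLE size factors and with library size only.

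Around ahr-1, 2 of the 100 nearest tested genes, 50 on each side in the order of a current annotation, changed at least 2-fold in the mutant, against 4.02% of all others (Fisher's exact test, two-sided p = 0.442).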
